A study of Zea mays with 24 samples.

How the data were processed

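Polyadenylated RNA of laser-microdissected maize leaf primordia was measured in 24 libraries, 3 in each of 8 groups: P7 blade, ligule and sheath through all cell layers (replicates 3 to 5), the same regions from the adaxial L1 (replicates 1 to 3), and P6 tissue of wild type and lg1-R (replicates 1 to 3). Per the labels, plants grew with 15 h of light at 25 °C and 9 h of dark at 20 °C, ligule pieces were rectangles 100 µm high placed on the preligule band by its shape, and blade and sheath pieces lay 50 µm above and below. RNA went through 2 rounds of linear amplification before Illumina library preparation. The labels do not say whether blade, ligule and sheath pieces with the same number came from the same plants, so libraries were treated as independent. In all layers some libraries of different regions deviated from their group means together, which the main fits leave out. Strandedness is not stated in the labels.

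The authors deposited a table of expected counts (estimated counts per gene) and a table of FPKM (fragments per kilobase and per 1e6 mapped fragments), with 109715 gene identifiers and 1 column per library. The submitters' notes name TopHat2 2.0.10 and Cuffdiff 2.1.1 without their roles, and the genome build and annotation are not given in the sources used here. Over all 109715 identifiers, zeros included and with no tolerance, 0.27% to 0.6% of the values of each library were not whole numbers, and the counts were rounded before the tests. Near-identical paralogs share reads, so their estimated counts are less certain. Names came from a table of the assembly Zm-B73-REFERENCE-NAM-5.0, in which 18258 identifiers matched 1 locus and 519 matched several and were not named; 2526 had a name other than a locus or clone code.

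Depth ran from 3818649 counts in ligule replicate 2 of the adaxial L1 to 52731783 in blade replicate 3 of all layers, so the floor of 3 counts equals 0.0531 to 0.736 CPM in a library. Over 24 pairs of replicates, the chi-square per degree of freedom lay between 11.6 and 142, so no pair differed by counting error alone. This does not exclude that a pair came from the same RNA, since amplification adds its own spread. The most abundant gene held 0.9% to 1.81% of the counts of a library. After the mean correlations with the own group were seen, and with no fixed rule, 4 libraries were picked as standing apart. They were sheath replicate 4 of all layers (0.922), ligule replicate 1 (0.873) and blade replicate 2 (0.893) of the adaxial L1 and wild-type replicate 1 of P6 (0.968), and all were kept. Ligule replicate 3 of all layers (0.947, against 0.959 and 0.958 in its group) was not picked, though it lay farther below its group than wild-type replicate 1 (against 0.979 and 0.975).

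Differences were tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM factors, filterByExpr with a smallest count of 10 and a smallest total of 15) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fit was made for each set of 9 P7 libraries, for the 6 P6 libraries, and for all 18 P7 libraries where layers were compared. The SE is the absolute log2 fold change divided by the square root of the F statistic. Where a group had no count, the fold is given as at least the ratio to 3 counts over that group, and where it had 1 to 3 counts as a ratio with a 95% interval of the counting error alone, which leaves out the spread between replicates. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), and the ligule genes in lg1-R with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

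The comparisons, the main tests, the alternatives and the rule for the genes named were chosen before the data were examined. The rule names every called member of the ligule and boundary list and lg1, lg2, lg3, lg4, kn1 and rs2 in any case; up to 10 named genes per direction with the largest change, an average log2 CPM of at least 3 and replicates that do not overlap; and up to 2 called members with the smallest p from each list. Its last part was added for the 2 comparisons of layers. Of the genes chosen so, those whose call was lost when a library was left out are not described singly. Exceptions are members of the ligule and boundary list and the genes among the results flagged for a closer look. The reference holds no gene descriptions, so the 28 lists were built from gene names, fixed after the names were seen and before any comparison of expression. The MADS-box, lignin synthesis, aquaporin, and starch and sugar lists were added at that point.

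The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 libraries, the same without that filter, a replicate block, each library left out in turn, a fit of all 24 libraries, a call in both pairwise comparisons, the lg1-R comparison without the chromosome carrying lg1, and other set tests. Leaving out together the libraries that stood apart was chosen after the data were seen. Overlaps were tested with Fisher's exact test, and 1 correlation over genes with 100000 permutations. Groupings of the same libraries, the real 1 included, were also fitted, 100 for each comparison of the ligule with the mean, the interaction and the layers, and 10 for each pairwise and P6 comparison.

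The tests were tested on simulated data with the sizes and spread of these libraries and 50 genes at each of 4 fold changes. The changed genes were drawn from those with a mean of at least 10 counts. For genes changed 2-, 4-, 8- and 16-fold, edgeR found 30%, 72%, 96% and 98% in all layers, 12%, 50%, 72% and 66% in the adaxial L1 and 32%, 86%, 98% and 96% in the P6 comparison, with 11, 8 and 10 false calls. Raw reads were not analysed here. Dixon's test for a library far from the others was not used here, since groups of 3 are too small for it.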

Results

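Polyadenylated RNA was sequenced from laser-microdissected leaf primordia of maize (Zea mays, inbred line B73) around the preligule band. From this strip of cells the ligule, the fringe between blade and sheath, grows out. The 24 libraries form 8 groups of 3. P7 primordia gave pieces of the band and of the pre-blade and pre-sheath tissue next to it, taken either through all cell layers or from the adaxial L1, the epidermis of the upper leaf side. These groups are called blade, ligule and sheath below. P6 primordia, 1 stage younger, gave a region 400 to 900 µm from the leaf base in wild-type siblings and in plants labelled lg1-R, a mutant allele of the liguleless gene lg1. Each library pooled 5 to 6 plants. The stated purpose was to find candidate genes for patterning at the boundary of blade and sheath and genes acting downstream of LG1.

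Total counts per library, in units of 1e6, lay between 21.7 and 52.7 in the all-layers blade, 19.3 and 51.3 in the ligule and 10 and 17.3 in the sheath. The adaxial L1 libraries were smaller, with 9.2 to 32.6 in the blade, 3.8 to 21.9 in the ligule and 6.2 to 18.1 in the sheath. The P6 libraries held 16 to 34.2 in wild type and 15 to 41 in lg1-R. Between 18460 and 31175 identifiers were detected per library. Levels are normalised CPM (counts per 1e6, mean ± SD, n = 3 libraries per group). Differences are log2 fold changes with their standard errors (SE). Adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Those of gene lists come from camera with a preset correlation, adjusted over the lists of a comparison.

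The ligule of all layers was first set against the mean of the log2 levels of blade and sheath. A gene can be called there though it differs from only the blade or only the sheath. The liguleless gene lg1 (GRMZM2G036297), an SBP-box transcription factor gene needed for ligule formation, stood at 8.58 ± 7.79 CPM in the ligule, against 0.0908 ± 0.082 in the blade and 0.129 ± 0.174 in the sheath (log2 fold change 6.28, SE 0.75, adjusted p = 0.00034). The WOX gene ns1 (GRMZM2G069028), named for its narrow-sheath mutant, and the NAC boundary gene CUC2 (GRMZM2G393433) had counts in the ligule and none in the blade or sheath. Against the floor of 3 counts over a group, ns1 was at least 64.1-fold higher than in the blade and 29.5-fold higher than in the sheath (2.65 ± 1.83 CPM, adjusted p = 0.00099). CUC2 was at least 55.8-fold and 25.7-fold higher (1.72 ± 0.617 CPM, adjusted p = 0.00056). The beta-glucosidase gene glu1 (GRMZM2G016890) stood at 323 ± 74.5 CPM in the ligule, 1.17 ± 0.295 in the blade and 11.6 ± 12.1 in the sheath (log2 fold change 6.43, SE 0.61, adjusted p = 0.00022). Among transcription factor genes, bHLH165 (GRMZM2G145579) rose from 0.111 ± 0.0244 and 4.81 ± 1.11 CPM to 28.2 ± 8.75 (5.26, SE 0.28, adjusted p = 1.7e-06). The SBP-box gene tga1 (GRMZM2G101511) rose by 4.2 (SE 0.47, adjusted p = 0.00021) and MADS34 (GRMZM2G137510) by 3.76 (SE 0.24, adjusted p = 2e-06).

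**Figure D1:**
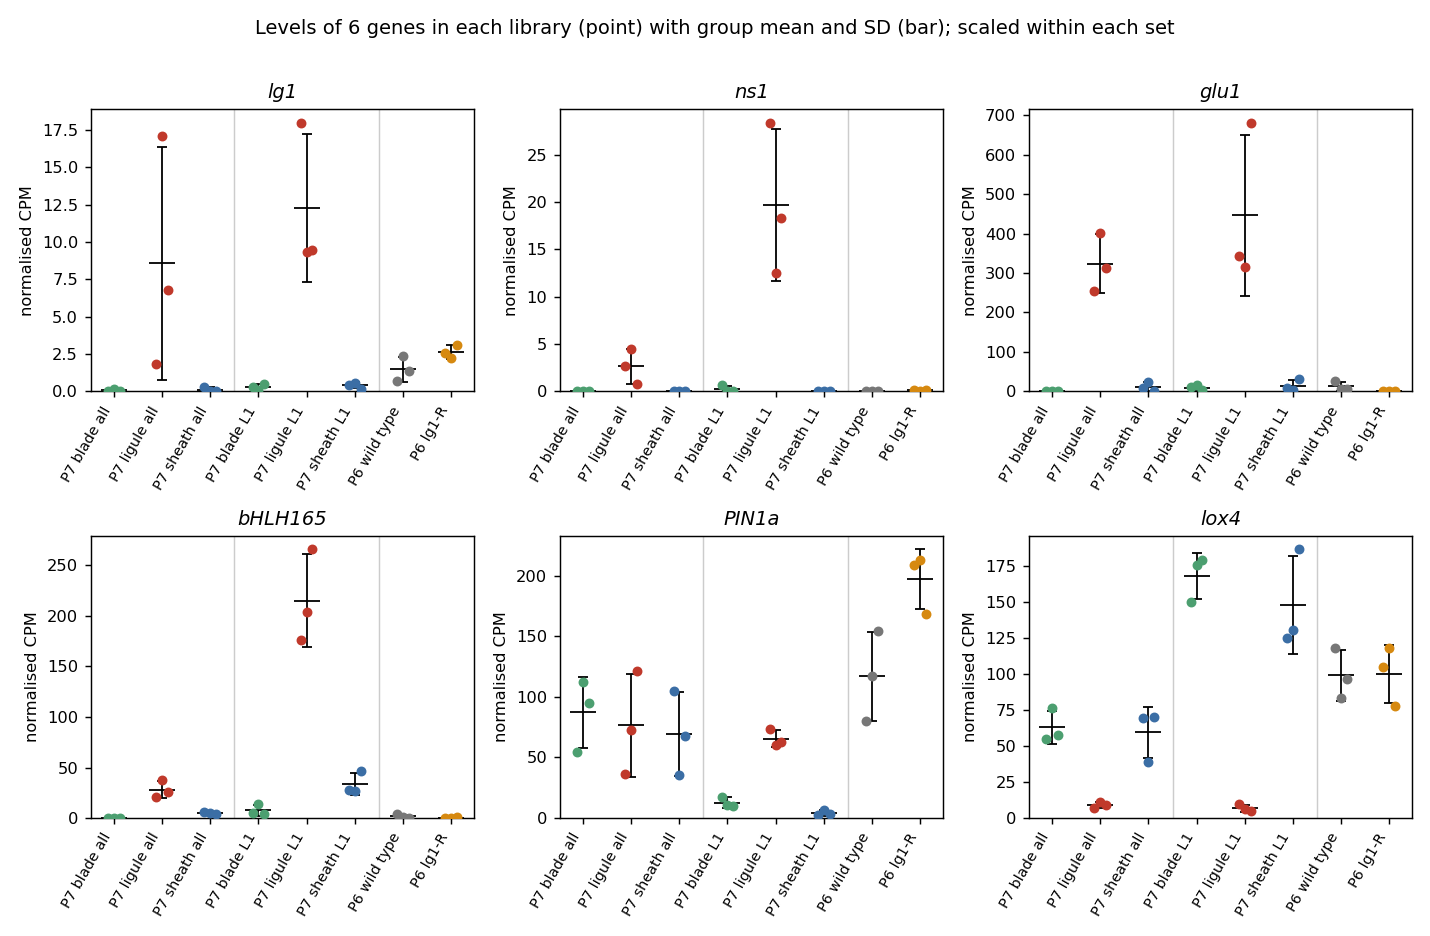
Normalised CPM (y axis) of lg1, ns1, glu1, bHLH165, PIN1a and lox4 in each library, by group on the x axis; points are libraries, bars the group mean and error bars the SD of 3 libraries, with the lower end drawn at 0 where the SD exceeds the mean, and levels are scaled within each set of libraries. In all layers lg1 averaged 8.58 in the ligule against 0.0908 in the blade, while in the adaxial L1 PIN1a averaged 65.5 in the ligule and 12.8 in the blade, with 69.3 to 87.2 in the all-layers groups.

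Other genes fell in the ligule of all layers. The YABBY gene yab14 (GRMZM2G005353) stood at 3.08 ± 0.506 CPM, against 30.4 ± 17.4 in the blade and 57.5 ± 18.2 in the sheath (log2 fold change -3.77, SE 0.46, adjusted p = 0.00039). The lipoxygenase gene lox4 (GRMZM2G109056) fell from 63 ± 11.5 and 59.5 ± 17.9 to 9.19 ± 2.11 CPM (-2.74, SE 0.27, adjusted p = 5.7e-05). The growth-regulating factor gene GRF7 (GRMZM5G850129) fell from 17.5 ± 2.14 and 22.9 ± 6.41 to 4.48 ± 1.97 CPM (-2.15, SE 0.31, adjusted p = 0.001). Further lower genes were bHLH30 (-3.41, SE 0.51, adjusted p = 0.0024) and CHI (-2.95, SE 0.35, adjusted p = 2e-04). So were thi1-2 (-2.36, SE 0.2, adjusted p = 2.1e-05), mips2, an inositol phosphate synthase gene (-2.31, SE 0.26, adjusted p = 0.00016), and MYB34 (-1.93, SE 0.22, adjusted p = 0.00018). Raised genes outside transcription factor families included gst41 (GRMZM2G097989), a glutathione transferase gene, from 656 ± 221 and 365 ± 138 to 3290 ± 1730 CPM (2.75, SE 0.32, adjusted p = 0.00021) and PYL7 (1.71, SE 0.24, adjusted p = 0.00089).

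Of 22205 genes tested in all layers, 608 were higher in the ligule than the mean of blade and sheath and 406 were lower at an adjusted p below 0.05. An unadjusted p below 0.05 was reached by 3669 genes, where 1110 would be reached by chance. The count of 1014 was 639 without ligule replicate 5, 1672 with DESeq2, 1890 with no filter on low counts and 404 where a call in both pairwise comparisons was required. With limma on log2(FPKM + 1), where low levels shrink toward 0, the log2 fold changes were 2.42 for lg1, 3.23 for bHLH165, 1.38 for CKX4b and 1.78 for dhn1. With no filter they were 1.69 for ns1, 1.28 for CUC2 and 1.28 for PIN5c, and all 7 genes were still called.

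Of the 31 tested ligule and boundary genes, 5 were called higher and 1 lower (adjusted over the list alone, 8 and 2; list median 0.13, adjusted p = 0.056). Besides lg1, ns1 and CUC2, the auxin transporter genes PIN5c and PIN1d were higher. PIN5c (GRMZM2G040911) had 175 counts in the ligule, 1 in the blade and 0 in the sheath (ratio over the blade 140, 95% counting interval 24.8 to 5570; adjusted p = 8e-04). PIN1d (GRMZM2G171702) rose from 115 ± 12.8 and 95.6 ± 13.7 to 198 ± 5.29 CPM (0.92, SE 0.16, adjusted p = 0.005). The lower member was zfl1 (GRMZM2G098813), a relative of LEAFY, with 3 counts in the ligule against 114 in the blade (blade over ligule 47.4, counting interval 15.8 to 233; adjusted p = 0.034). Its call was lost without blade replicate 4 or 5, ligule replicate 3 or 5, or sheath replicate 5, and with limma or in a fit of all 24 libraries. Its log2 fold change ranged from -5.12 to -0.78 over all settings. No call was made for lg2, a bZIP gene of ligule formation (0.29, SE 0.23, adjusted p = 0.6). The KNOX gene lg3 was not called (2.7, SE 1.01, adjusted p = 0.2, but 0.00014 with no filter on low counts and between 0.00014 and 0.5 over all settings). Nor was rs2 (-0.16, SE 0.2, adjusted p = 0.78), whose product keeps KNOX genes off in leaves. The KNOX genes kn1, with 32, 35 and 16 counts in blade, ligule and sheath, and lg4, with 0, 4 and 1, were too low to be tested.

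Cytokinin genes shifted upward in the ligule of all layers, with 5 of 26 tested members called higher and none lower (adjusted over the list alone, 8 and 0; median 0.45, adjusted p = 3.4e-05). With an estimated correlation the adjusted p was 0.05, above the threshold before rounding. The member with the largest rise described here was CKX4b (GRMZM2G024476), a cytokinin oxidase gene (3.84, SE 0.56, adjusted p = 0.0012). Of 44 auxin response and transport genes 7 were called higher and 2 lower (adjusted over the list alone, 13 and 4; median 0.31, adjusted p = 0.014; adjusted p = 0.38 with an estimated correlation). That list call was also lost without sheath replicate 4 (median 0.31, adjusted p = 0.065, with leave-one-out values from 0.0071 to 0.065). The lower members included AUX32 (-2.42, SE 0.43, adjusted p = 0.0047), not called in a fit of all 24 libraries and at -1.07 with limma on log2(FPKM + 1). Of 21 SBP-box genes 6 were called higher, lg1 and tga1 among them, and 1 lower (adjusted over the list alone, 7 and 3; median 0.38, adjusted p = 0.041; adjusted p = 0.58 with an estimated correlation). The call of the SBP-box list was lost without blade replicate 3, ligule replicate 4 or sheath replicate 4. The adjusted p was then 0.098, 0.12 and 0.07, with leave-one-out values from 0.014, and the median without ligule replicate 4 was 0.17.

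Cytosolic ribosomal protein genes shifted downward in the ligule of all layers, with 0 of 34 called higher and 2 lower (adjusted over the list alone, 0 and 11; median -0.57, adjusted p = 3.4e-13; adjusted p = 0.38 with an estimated correlation). The HD-ZIP IV genes, epidermis markers, also shifted downward, with 2 of 7 called lower (median -0.52, adjusted p = 0.0078; adjusted p = 0.38 with an estimated correlation). Among these was ocl1 (GRMZM2G026643), which fell from 223 ± 33.5 and 199 ± 24.8 to 102 ± 10.9 CPM (-1.05, SE 0.19, adjusted p = 0.005). No other list was called by camera in this comparison. Among regulator lists the medians were 0.26 for 3 KNOX genes (0 called), 0.15 for 11 NAC genes (1 higher), 0.02 for 6 LOB domain genes (1 higher) and 0.19 for 14 MADS-box genes (2 higher). The 10 YABBY and KANADI genes had a median of 0.25 and a mean of -0.13 (1 lower, yab14), the 27 growth regulation genes a median of -0.27 (2 higher, 4 lower), the 3 gibberellin genes -0.1 (0 called) and the 31 jasmonate and lipoxygenase genes -0.11 (2 higher, 5 lower). The 2 HD-ZIP III genes (median 0.34) and the 2 stomatal genes (-0.14) were too few for a list test, and none of them was called.

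Lists of growth and metabolism gave medians of 0.12 for 11 histone genes and 0.01 for 38 cell cycle genes, with 0 called in either. The median was 0.44 for 7 cell wall loosening genes, 0.21 for 16 cell wall synthesis genes and -0.32 for 7 lignin synthesis genes, again with 0 called. It was 0.18 for 17 genes of the light reactions (2 higher), 0.21 for 9 genes of carbon fixation and C4 (2 higher), 0.39 for 11 aquaporin genes (1 higher, 1 lower) and 0.11 for 20 genes of starch and sugar metabolism (1 higher, 1 lower). The 9 cuticle genes had a median of 0.11 and the 7 vascular genes of 0.56, with 0 called in either. Of the 20 heat shock and stress genes, taken as signs of RNA quality, 2 were higher and 2 lower (median -0.13). The dehydrin gene dhn1 (GRMZM2G079440) had 395 counts in the ligule, 0 in the blade and 1 in the sheath (at least 106-fold over the blade; adjusted p = 4.1e-05). The heat shock gene hsp101 fell (-1.78, SE 0.25, adjusted p = 0.00079).

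The same comparison in the adaxial L1 asks which of these differences are found in the epidermis of the band. There lg1 stood at 12.3 ± 4.93 CPM in the ligule, 0.294 ± 0.176 in the blade and 0.413 ± 0.213 in the sheath (5.07, SE 0.63, adjusted p = 0.00024). The gene ns1 reached 19.7 ± 8.05 CPM, against 0.221 ± 0.383 in the blade and 0 in the sheath (at least 249-fold over the sheath, adjusted p = 0.00043). The auxin transporter gene PIN1a (GRMZM2G098643) rose to 65.5 ± 6.99 CPM, from 12.8 ± 4.33 in the blade and 4.24 ± 2.24 in the sheath (3.13, SE 0.32, adjusted p = 6.2e-05). Of 28 ligule and boundary genes 5 were called higher and 6 lower (adjusted over the list alone, 8 and 8; median -0.01, adjusted p = 0.98). PIN1d rose (1.58, SE 0.3, adjusted p = 0.005). The lower members included the LOB domain gene IG1 (GRMZM2G118250; -2.18, SE 0.38, adjusted p = 0.0027) and the DELLA gene D8 (GRMZM2G144744; -1.02, SE 0.17, adjusted p = 0.0021). The SBP-box gene ub2 was lower too (GRMZM2G160917; -2.57, SE 0.39, adjusted p = 0.001). The gene rs2 (GRMZM2G403620) fell from 46 ± 9.86 and 39.4 ± 9.1 to 10.7 ± 1.75 CPM (-2, SE 0.29, adjusted p = 0.00092). The calls of 3 members hung on single libraries, with log2 fold changes over all settings given in brackets. They included lbl1, a gene of small RNA biogenesis (0.8, SE 0.2; 0.53 to 0.98), lost without ligule replicate 1 or 2 or sheath replicate 2 or 3 and in a fit of all 24 libraries, and DLF1 (-1.37, SE 0.32; -1.66 to -1.2), lost without ligule replicate 1 or 3. The call of lgn, a kinase gene of ligule formation (-1.76, SE 0.39; -1.96 to -1.4), was lost without ligule replicate 2.

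In the adaxial L1 lg2 was not called (0.97, SE 0.3, adjusted p = 0.069), except with DESeq2, with no filter, in a fit of all 24 libraries and without blade replicate 2, where it was 1.18. No call was made for lg3 (0.04, SE 1.74, adjusted p = 0.99) or kn1 (-0.66, SE 1.49, adjusted p = 0.88), and lg4 had no count there. The gene named lg4b (GRMZM5G832409) had 15 counts in the ligule of the adaxial L1, where its SD exceeded its mean. It had 0 counts in the blade and the sheath there. Other named genes that rose included glu1, from 9.89 ± 7.18 and 14.3 ± 15.2 to 446 ± 204 CPM (5.24, SE 0.66, adjusted p = 0.00057), and CKX4b (5.11, SE 0.93, adjusted p = 0.0039, and 7.82 without sheath replicate 3). Rises were found for sbp3 (3.96, SE 0.8, adjusted p = 0.0076), bHLH165, to 216 ± 46.1 CPM (3.78, SE 0.34, adjusted p = 2.2e-05), and tga1 (3.55, SE 0.52, adjusted p = 0.00085). Rises were also found for EREB208 (3.28, SE 0.4, adjusted p = 0.00021), ARF23 (2.92, SE 0.47, adjusted p = 0.0017), GR2b (2.7, SE 0.48, adjusted p = 0.0031) and NAC61 (2.29, SE 0.28, adjusted p = 0.00023). Among lower genes dehydrin3 (GRMZM2G373522) fell from 1070 ± 148 and 336 ± 27 to 5.82 ± 1.47 CPM (-6.64, SE 0.25, adjusted p = 1.2e-08). The gene mips2 fell from 55.9 ± 11 and 8.75 ± 3.27 to 0.155 ± 0.0815 CPM (-7.3, SE 0.54, adjusted p = 6.8e-06). GRF7 was lower (-7.07, SE 0.74, adjusted p = 7e-05; -11.04 without ligule replicate 3). On the log2 scale bHLH30 fell by 4.9 (SE 0.43, adjusted p = 1.9e-05), PMP3 by 4.58 (SE 0.45, adjusted p = 4.3e-05) and acco20 by 4.09 (SE 0.51, adjusted p = 0.00025).

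Cytokinin genes were again shifted upward, with 5 of 23 called higher and 0 lower (adjusted over the list alone, 8 and 0; median 0.58, adjusted p = 3e-04; adjusted p = 0.074 with an estimated correlation). Among them were the response regulator genes RR6 (GRMZM2G129954; 3.4, SE 0.46, adjusted p = 0.00044) and abph1 (GRMZM2G035688). The latter stood at 13.7 ± 3.72 CPM in the ligule, 11.7 ± 5.01 in the blade and 0 in the sheath. Cell wall loosening genes shifted upward, with 2 of 5 called higher (adjusted over the list alone, 3; median 0.85, adjusted p = 0.0047; adjusted p = 0.074 with an estimated correlation). The expansin gene expa2 (GRMZM2G105844) rose from 380 ± 33.3 and 234 ± 84.5 to 1100 ± 154 CPM (1.88, SE 0.21, adjusted p = 1e-04). EXPA5 rose as well (2.3, SE 0.29, adjusted p = 0.00028). The median of the list was 1.83 without blade replicate 3, 1.74 without sheath replicate 2 and 0.39 with no filter on low counts, and the call was kept in each. Jasmonate and lipoxygenase genes shifted downward, with 6 of 25 called lower and 1 higher (adjusted over the list alone, 10 and 1; median -0.7, or -1.23 with no filter, adjusted p = 0.00046; adjusted p = 0.074 with an estimated correlation). Of these lox4 fell from 169 ± 15.8 and 148 ± 34.4 to 6.86 ± 2.52 CPM (-4.53, SE 0.31, adjusted p = 3.6e-06), and lox5 by 2.37 on the log2 scale (SE 0.23, adjusted p = 4e-05). HD-ZIP IV genes shifted downward, with 4 of 7 called lower (adjusted over the list alone, 5; median -1.02, adjusted p = 3.5e-05; adjusted p = 0.074 with an estimated correlation). Examples were ocl1 (-1.3, SE 0.19, adjusted p = 0.00091) and ocl3 (-1.65, SE 0.25, adjusted p = 0.00098). Cell wall synthesis genes shifted downward too (2 of 12 called lower, median -0.67, adjusted p = 0.0075; adjusted p = 0.074 with an estimated correlation), with CslF6-1 as an example (-1.25, SE 0.23, adjusted p = 0.0043).

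A further 3 list calls of the adaxial L1 were lost when a library was left out. Histone genes had a median of 0.25 with 0 of 10 called (adjusted p = 0.017; adjusted p = 0.18 with an estimated correlation). The call was lost without ligule replicate 1 or 3 (adjusted p = 0.052 and 0.069, with leave-one-out values from 0.0072). Lignin synthesis genes had a median of -1.3 with 1 of 4 called lower, PAL1 (-1.72, SE 0.27; list adjusted p = 0.017; adjusted p = 0.1 with an estimated correlation). This call was lost without ligule replicate 1 (adjusted p = 0.052, with leave-one-out values from 0.0072), and the median was -2.06 without ligule replicate 3. Genes of starch and sugar metabolism had a median of -1.14 with 1 of 16 called lower. This was the sucrose synthase gene sus1, which fell from 6080 ± 293 and 7470 ± 2240 to 1290 ± 210 CPM (-2.38, SE 0.19, adjusted p = 1.2e-05). The call of that list (adjusted p = 0.014; adjusted p = 0.079 with an estimated correlation) was lost without ligule replicate 2 or 3 (adjusted p = 0.087 and 0.063, with leave-one-out values from 0.01). The median was -0.67 without ligule replicate 2 and -0.71, -0.74 and -0.74 without sheath replicate 1, 2 and 3. Auxin genes were not called as a list there (8 of 33 higher, 3 lower; median 0.1, adjusted p = 0.057). Nor were SBP-box genes (5 of 21 higher, 1 lower; median 0.09, adjusted p = 0.28) or growth regulation genes (4 of 24 higher, 6 lower; median -0.64, adjusted p = 0.13).

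Of 18761 genes tested in the adaxial L1, 554 were called higher and 897 lower in the ligule, with 3748 at an unadjusted p below 0.05 against 938 by chance. The count of 1451 was 826 without ligule replicate 2, the library with the fewest counts, and 898 without ligule replicate 3. It was 2425 with DESeq2, 2317 with no filter on low counts, 3858 in a fit of all 24 libraries and 631 where a call in both pairwise comparisons was required. With limma on log2(FPKM + 1) the log2 fold changes of genes low in some groups were nearer 0 and still called, at 2.92 for lg1, 4.12 for ns1, 2.44 for abph1, -3.65 for mips2 and -3.68 for GRF7.

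**Figure D2:**
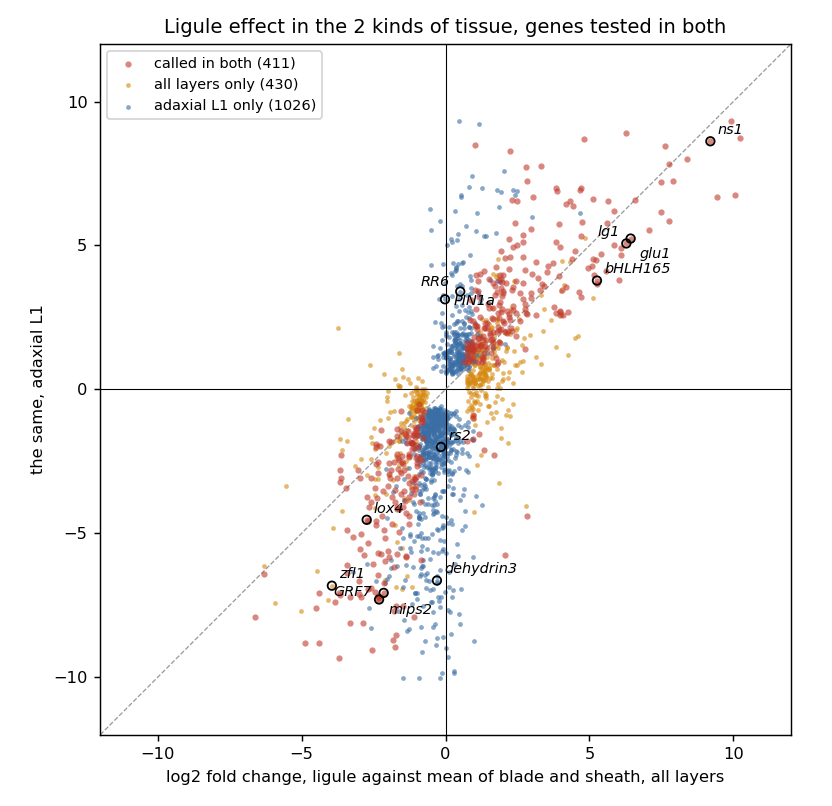
Log2 fold change of the ligule against the mean of blade and sheath in all layers (x axis) and in the adaxial L1 (y axis), with 1 point per gene called in either set and colours for calls in both sets or in 1 of them. Of 18670 genes tested in both sets, 228 were called higher in both and 174 lower in both, and named points such as PIN1a and dehydrin3 lie near 0 on the x axis.

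The ligule genes of both sets overlapped. Of 18670 genes tested in both, 492 were called higher in all layers and 541 in the adaxial L1. Of these 228 were in both lists where 14.3 would be shared by independent lists (Fisher's exact test, two-sided, p = 3.6e-231). For lower genes 174 were shared between lists of 349 and 896, where 16.7 would be by independent lists (Fisher's exact test, p = 5.3e-137). These p-values treat genes as independent replicates, which they are not, and the all-layers pieces also hold the adaxial L1. Only 9 genes were called higher in all layers and lower in the adaxial L1, and 0 the other way. Called the same way in all 4 pairwise comparisons of the ligule were 63 genes in the higher direction and 66 in the lower. The named ones were ns1, glu1, lg1, bHLH165, gst31 and PIN1d among the higher. Among the lower they were lox4, mips2, GRF7, ocl1, ocl3, MYB34, CHI, bHLH30, bHLH139, CYP714B3, acco20 and AR2.

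Against the blade alone, 608 genes were higher and 446 lower in the ligule of all layers (of 22205 tested), and against the sheath alone 315 were higher and 304 lower. In the adaxial L1 (18761 tested) these counts were 423 and 793 against the blade, and 400 and 758 against the sheath. Both comparisons shared 236 higher and 168 lower genes in all layers, where independent lists would share 8.63 and 6.11. In the adaxial L1 they shared 169 and 462, where independent lists would share 9.02 and 32. Both use the same 3 ligule libraries, which cannot be divided into parts of at least 2, so both lists carry the same errors of the ligule libraries. In 5 simulations per set with no change at all, no more than 2 genes were called and 0 were shared, which is too few to show how far shared libraries raise the overlap of longer lists. The all-layers count against the blade, 1054, was 691, 598 and 660 without blade replicate 3, 4 and 5, 677 without ligule replicate 5 and 1600 without sheath replicate 4. The all-layers count against the sheath, 619, was 374 without ligule replicate 5. In the adaxial L1 the count against the blade, 1216, was 808 without blade replicate 1, 706 without ligule replicate 2 and 761 without ligule replicate 3. The count against the sheath, 1158, was 640 and 724 without ligule replicate 2 and 3.

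Blade and sheath of all layers were compared directly across the boundary. The glutamine synthetase gene GLN6 (GRMZM2G050514) stood at 115 ± 6.08 CPM in the sheath and 0.208 ± 0.102 in the blade (blade minus sheath -8.96, SE 0.37, adjusted p = 6e-08), with 25.9 ± 5.56 in the ligule between them. The aquaporin gene NIP2-3 (GRMZM2G081239) followed the same order, at 36.7 ± 14.7 CPM in the sheath and 0.0912 ± 0.0499 in the blade (-8.79, SE 0.85, adjusted p = 0.00032). Also higher in the sheath were bHLH165 (-5.42, SE 0.42, adjusted p = 2.6e-05) and the heat shock gene Hsp70 (GRMZM2G310431; -3.79, SE 0.43, adjusted p = 7e-04). So were ial1 (-3.43, SE 0.45, adjusted p = 0.0016) and gl4a, a cuticle wax gene (-3.14, SE 0.36, adjusted p = 0.00053). Higher in the blade was incw1 (GRMZM2G139300), a cell wall invertase gene with 953 counts against 2 (ratio 219, 95% counting interval 60.4 to 1810; adjusted p = 2.6e-05). So was abph1, with 374 counts against 1 (ratio 172, interval 30.7 to 6810; adjusted p = 0.001). No call was made for lg1 (-0.75, SE 1.3, adjusted p = 0.96), lg2 (0.2, SE 0.27, adjusted p = 0.94), lg3 (-2.03, SE 1.42, adjusted p = 0.81) or rs2 (-0.07, SE 0.23, adjusted p = 0.98), and kn1 and lg4 were too low to be tested.

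Photosynthesis genes were lower in the blade than in the sheath of all layers. Of 17 genes of the light reactions 4 were called lower in the blade and 0 higher (adjusted over the list alone, 8 and 0; median -1.4, adjusted p = 3.7e-11; adjusted p = 0.034 with an estimated correlation). The antenna protein gene CP24 stood at 0.746 ± 0.257 CPM in the blade and 8.68 ± 2.31 in the sheath (-3.51, SE 0.42, adjusted p = 0.00088). Another was psaN (-1.86, SE 0.27, adjusted p = 0.0038), which was not called in a fit of all 24 libraries. Of 9 genes of carbon fixation and C4, 3 were called lower (adjusted over the list alone, 4 lower and 1 higher; median -0.62, adjusted p = 0.00085; adjusted p = 0.088 with an estimated correlation). The Rubisco small subunit gene rbcS (GRMZM2G098520) stood at 8.55 ± 1.28 and 41.8 ± 3.02 CPM (-2.29, SE 0.23, adjusted p = 0.00023) and was also not called in that fit. Aquaporin genes were lower in the blade as well (2 of 11 called; adjusted over the list alone, 3; median -0.79, adjusted p = 3.4e-06; adjusted p = 0.25 with an estimated correlation). The 10 YABBY and KANADI genes had a median of -0.78 with 0 called (adjusted over the list alone, 2 lower; adjusted p = 0.0012; adjusted p = 0.3 with an estimated correlation). This call was lost without sheath replicate 3 (adjusted p = 0.051, with leave-one-out values from 2.5e-05). Ribosomal protein genes had a median of 0.19 with 0 called (adjusted p = 0.0037; adjusted p = 0.7 with an estimated correlation). The call was lost without blade replicate 4 or sheath replicate 5 (adjusted p = 0.14 and 0.34, with leave-one-out values from 4.2e-05). Its median was 0.32 without blade replicate 5, 0.37 without sheath replicate 4 and 0.09 without sheath replicate 5. With no filter on low counts the medians were -1.19 for carbon fixation and C4 and -0.39 for aquaporins, both still called.

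In all, 112 genes were higher in the blade and 238 higher in the sheath of all layers, with 1997 at an unadjusted p below 0.05 against 1110 by chance. The count of 350 was 168, 151 and 113 without blade replicate 3, 4 and 5, and 163 without sheath replicate 5. It was 689 with DESeq2, 827 with no filter on low counts, 166 in a fit of all 24 libraries and 185 with a replicate block. The block used the replicate numbers as labelled, which may be wrong for sheath replicates 3 and 4. With limma on log2(FPKM + 1) the calls stayed and the differences shrank, to -4.64 for NIP2-3, -1.95 for bHLH165, -2.14 for ial1, 2.51 for incw1 and 2.57 for abph1.

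In the adaxial L1, GLN6 showed 398 ± 52.2 CPM in the sheath and 0.782 ± 0.392 in the blade (-9.12, SE 0.38, adjusted p = 3.8e-08). NIP2-3 was lower in the blade as well (-7.48, SE 0.51, adjusted p = 3.9e-06). The YABBY gene yabby15 (GRMZM2G529859) stood at 382 ± 67.6 CPM in the sheath and 39.4 ± 6 in the blade (-3.28, SE 0.3, adjusted p = 9.1e-05). The AP2 gene ids1 (GRMZM5G862109), of the ligule and boundary list, was also higher in the sheath (-1.97, SE 0.32, adjusted p = 0.0056). Further genes higher in the sheath were aos1, of jasmonate synthesis (-6.52, SE 0.75, adjusted p = 0.00054), GST38 (-6.39, SE 0.79, adjusted p = 0.00077) and Hsp70 (-5.42, SE 0.5, adjusted p = 1e-04). HIT2 (-4.05, SE 0.57, adjusted p = 0.002) and SMR4 (-3.63, SE 0.45, adjusted p = 0.00081) went the same way. Higher in the blade were abph1, at least 121-fold over the sheath, where it had no count (adjusted p = 0.00041), and mips2 (2.66, SE 0.38, adjusted p = 0.0021). Others were OFP16 (2.41, SE 0.36, adjusted p = 0.0033) and the SBP-box gene sbp29 (1.99, SE 0.29, adjusted p = 0.0023). No call was made for lg1 (-0.44, SE 0.79, adjusted p = 0.9), lg2 (0.52, SE 0.36, adjusted p = 0.64) or lg3 (2, SE 2.18, adjusted p = 0.8). The same held for kn1 (4.95, SE 1.84, adjusted p = 0.26) and rs2 (0.23, SE 0.3, adjusted p = 0.85), though kn1 was called with no filter and in a fit of all 24 libraries. With limma on log2(FPKM + 1) aos1 was -2.95, GST38 -3.71 and abph1 4.1, all called.

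Histone genes were higher in the blade than in the sheath of the adaxial L1, with 2 of 10 called (adjusted over the list alone, 6; median 0.68, adjusted p = 1.2e-06; adjusted p = 0.084 with an estimated correlation). The histone H3 gene H3C2 (GRMZM2G401581) stood at 1010 ± 94.2 and 444 ± 12.2 CPM (1.18, SE 0.16, adjusted p = 0.0019), which was not called in a fit of all 24 libraries. Aquaporin genes were lower in the blade (1 of 8 called; adjusted over the list alone, 4; median -1.17, adjusted p = 0.00076; adjusted p = 0.084 with an estimated correlation). The aquaporin median was -0.49 and -1.8 without blade replicate 2 and 3, -0.6 without ligule replicate 1, -0.35 and -0.41 without sheath replicate 1 and 3, and -0.37 with no filter, each still called. Jasmonate genes were lower in the blade too (1 called lower; median -0.44, adjusted p = 0.004; adjusted p = 0.15 with an estimated correlation). The cytokinin list (2 called higher; median 0.35, adjusted p = 0.048; adjusted p = 0.15 with an estimated correlation) was lost in most settings. It had no call without any of the 3 blade or 3 ligule libraries, sheath replicate 1 or sheath replicate 3, with leave-one-out adjusted p-values between 0.038 and 0.14 and medians between 0.23 (without sheath replicate 1) and 0.58 (without blade replicate 2). Of the genes of the light reactions 6 could be tested, with a median of 0.17 (adjusted p = 0.95). In all, 161 genes were higher in the blade and 206 in the sheath, with 2329 at an unadjusted p below 0.05 against 938 by chance. The count of 367 was 201, 240 and 231 without blade replicate 1, sheath replicate 2 and sheath replicate 3, and 993 with DESeq2, each with more genes higher in the sheath. It was 906 with no filter (480 higher in the blade, 426 in the sheath) and 1786 in a fit of all 24 libraries (1011 and 775). With the all-layers calls, 28 genes were shared among those higher in the blade (0.737 by independent lists, Fisher's exact test, two-sided, p = 2.5e-37). Among those higher in the sheath 82 were shared (2.05 by independent lists, Fisher's exact test, p = 2.2e-115). Both p-values have the same limit as those for the overlap of the ligule genes.

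The libraries labelled lg1-R were compared with wild type at P6 to find genes downstream of LG1. The targeted gene lg1 itself had 23, 41 and 37 counts in the wild-type libraries (0.693, 2.37 and 1.38 CPM) and 39, 31 and 138 in those labelled lg1-R (2.56, 2.25 and 3.13 CPM). It was thus not lower in the libraries labelled lg1-R (0.89, SE 0.43, adjusted p = 0.78). The nature of the lesion is not given in the sources used here, so transcript level does not check these labels and every direction below rests on them. The beta-glucosidase gene glu1, raised in the ligule of both P7 sets, averaged 13 ± 11.6 CPM in wild type and 0.615 ± 0.526 in lg1-R, a difference that did not pass the test (-4.16, SE 0.67, adjusted p = 0.082). Values of bHLH165 (-1.65, SE 0.77, adjusted p = 0.77), lg2 (-0.24, SE 0.28, adjusted p = 0.93), lg3 (0.33, SE 0.69, adjusted p = 0.96) and rs2 (0.21, SE 0.23, adjusted p = 0.92) did not pass either, and kn1 and lg4 had 40 or fewer counts in all and were not tested. PIN1a averaged 117 ± 36.8 CPM in wild type and 197 ± 24.9 in lg1-R, a difference that was not called either. Genes raised in the P7 ligule were low in the P6 wild type, with levels scaled within each set. There ns1 had 2 counts, against 240 in the P7 ligule of all layers. The means were 1.48 CPM against 8.6 for lg1, 13 against 323 for glu1 and 1.75 against 28.2 for bHLH165. Low levels leave less room to detect a fall in lg1-R.

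Of 21249 genes tested between lg1-R and wild type, edgeR called 1, GRMZM2G095725, which was higher in lg1-R (2.1, SE 0.22, adjusted p = 0.019). It has no name and was chosen after its values were seen. DESeq2 called 80 higher and 70 lower, and an unadjusted p below 0.05 in edgeR was reached by 1401 genes against 1062 by chance. The edgeR count was 58 without wild-type replicate 3 (10 higher, 48 lower), 43 without lg1-R replicate 3 (41 higher, 2 lower) and 0 without each of the other 4 libraries in turn. It was 482 with no filter on low counts. In simulated libraries of the same size and spread, edgeR found 86% of genes changed 4-fold and 32% of those changed 2-fold. The changed genes there were drawn from those with a mean of at least 10 counts. In the real libraries GRMZM2G366873 (-5.03) and glu1 (-4.16) did not pass edgeR (adjusted p = 0.082 for each). The simulated shares thus do not show that few genes changed 4-fold or more.

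The genes called in the ligule of P7 leaves were then examined as sets in the P6 comparison. Of the 608 genes higher in the ligule of all layers 492 could be tested, and 76.6% of them lay below 0 in lg1-R (median -0.27, 111 lower and 7 higher at an unadjusted p below 0.05), where the median of all tested genes was -0.009 with 51.3% below 0. With fry, which tests whether a set's genes move together in 1 direction, p was 0.081 (adjusted over 8 sets, 0.65). Camera, which compares the set with the other genes, gave an adjusted p = 1.9e-15 over the sets with a preset correlation and an adjusted p = 0.75 with an estimated correlation. The 387 tested genes lower in the ligule of all layers had a median of 0.11 (38% below 0; adjusted p = 0.78 by fry). The 485 higher in the ligule of the adaxial L1 had a median of -0.02 (53% below 0; adjusted p = 0.78) and the 886 lower there 0.05 (45.9% below 0; adjusted p = 0.78). Without wild-type replicate 1 the first median was -0.12 and without wild-type replicate 3 it was -0.36, and over all 6 libraries left out in turn it stayed between those values. Genes called higher in the ligule by both pairwise comparisons of all layers had a median of -0.52 in lg1-R. These sets were chosen on P7 libraries that are separate from the P6 ones.

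**Figure D3:**
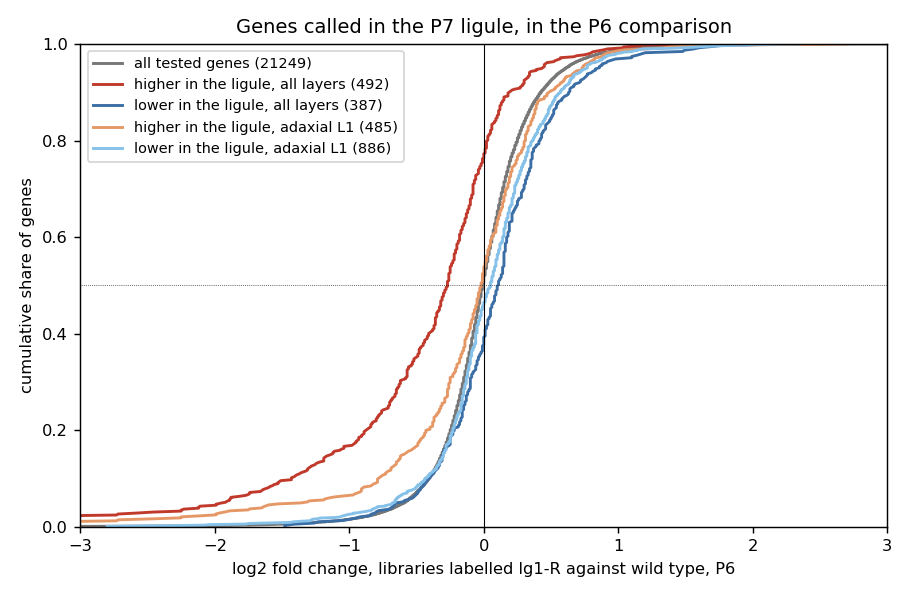
Cumulative share of genes (y axis, as a fraction) against the log2 fold change of lg1-R against wild type at P6 (x axis). There is 1 line for all tested genes and 1 for each of 4 sets of ligule genes from the P7 comparisons. The line of genes higher in the ligule of all layers lies left of the others, with a median of -0.27 against -0.009 for all genes.

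Among the gene lists, 3 were called between lg1-R and wild type by camera, each with 0 members called singly and each lost with an estimated correlation. YABBY and KANADI genes had a median of 0.21 over 11 members (adjusted over the list alone, 3 higher; adjusted p = 0.04), lost without wild-type replicate 2 or 3 (medians 0.14 and 0.06) and without lg1-R replicate 3, where the median was -0.05. Without wild-type replicate 1 it was 0.35. Lignin synthesis genes had a median of 0.7 over 7 members (adjusted over the list alone, 3 higher; adjusted p = 0.02), lost without lg1-R replicate 3 (median 0.44). Aquaporin genes had a median of 0.22 over 9 members (adjusted over the list alone, 3 higher; adjusted p = 0.02), lost without wild-type replicate 2 or 3 (medians 0.27 and 0.12) and lg1-R replicate 1 or 3 (0.18 and 0.49). Without wild-type replicate 1 it was 0.5 and without lg1-R replicate 2 it was 0.34, both still called. All 3 had an adjusted p = 0.84 with an estimated correlation, and the leave-one-out values ran from 0.00034 to 0.63.

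Whether the ligule difference itself differed between the adaxial L1 and all layers was tested as an interaction over the 18 P7 libraries. The difference for PIN1a was 3.1 larger in the adaxial L1 (SE 0.54, adjusted p = 0.0021), with -0.02 in all layers and 3.13 in the L1. Scaled over these libraries PIN1a averaged 80.4, 70.9 and 64.4 CPM in blade, ligule and sheath of all layers and 14.1, 69.4 and 4.58 in the adaxial L1. That for RR6 was 2.84 larger (SE 0.48, adjusted p = 0.0015). In the other direction stood dehydrin3 (-6.38, SE 0.38, adjusted p = 2.9e-09), with -0.3 in all layers, and mips2 (-5.08, SE 0.55, adjusted p = 3.3e-05). So did GRF7 (-4.95, SE 0.71, adjusted p = 0.00036; -9.74 without ligule replicate 3 of the adaxial L1 and -1.9 with limma on log2(FPKM + 1)). GRAS19 (-3.35, SE 0.44, adjusted p = 0.00014) and rs2 (-1.88, SE 0.32, adjusted p = 0.0019) followed. Of 22334 genes tested 80 had a higher and 426 a lower ligule difference in the adaxial L1, with 2751 at an unadjusted p below 0.05 against 1117 by chance. The count of 506 was 1003 with DESeq2, 1029 with no filter and 816 in a fit of all 24 libraries. Jasmonate genes differed as a list (median -1.16, or -0.87 with genes at 0 set to their bound; adjusted p = 0.00077; adjusted p = 0.22 with an estimated correlation). So did ribosomal protein genes (median 0.52, adjusted p = 7.7e-08; adjusted p = 0.25 with an estimated correlation). Genes of starch and sugar metabolism also did (median -1.24, or -0.91 with genes at their bound; adjusted p = 0.003; adjusted p = 0.054 with an estimated correlation).

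The mean of the 3 regions was also compared between the adaxial L1 and all layers. The P7 pieces of each kind were separate sets of libraries, so layer and set cannot be separated here, and the median of all genes lay at -0.153. All 7 HD-ZIP IV genes were higher in the adaxial L1 (median 1.51, adjusted p = 7.1e-10; adjusted p = 0.009 with an estimated correlation). Examples were ocl4 (2.09, SE 0.18, adjusted p = 2.7e-08) and ocl5 (1.72, SE 0.13, adjusted p = 4e-09). Of 10 cuticle genes 4 were higher with 0 lower (adjusted over the list alone, 6; median 0.89, or 0.29 with no filter, adjusted p = 0.00086; adjusted p = 0.015 with an estimated correlation), an example being the lipid transfer gene LTP3 (1.74, SE 0.13, adjusted p = 4.2e-09). The HD-ZIP III gene rld2, an adaxial marker, was higher too (1.21, SE 0.12, adjusted p = 2e-07), as was IG1 (2.81, SE 0.25, adjusted p = 3e-08). All 10 YABBY and KANADI genes were lower in the adaxial L1 (median -7.53, or -5.85 with genes at 0 set to their bound; adjusted p = 2.2e-10; adjusted p = 0.009 with an estimated correlation). YAB6 had no count in the ligule of the adaxial L1 and was at least 268-fold higher in the all-layers blade. Photosynthesis genes were lower (13 of 16 of the light reactions; median -5.31, or -4.46 at the bound; adjusted p = 8.2e-09; adjusted p = 0.0013 with an estimated correlation). So were genes of carbon fixation and C4 (5 of 8; median -5.99, or -3.8 at the bound; adjusted p = 0.00033; adjusted p = 0.021 with an estimated correlation). The same was found for lignin synthesis (6 of 7; median -4.89, adjusted p = 0.00011; adjusted p = 0.063 with an estimated correlation). Of 7 vascular genes 3 were lower and 0 higher (median -2.99, adjusted p = 0.12). In all, 2863 genes were higher and 4673 lower in the adaxial L1, of 22334 tested, with 9686 at an unadjusted p below 0.05 against 1117 by chance. The split depended on the values used, with 1474 higher and 7008 lower by limma on log2(FPKM + 0.1), 1596 and 6927 on log2(FPKM + 1), and 1449 and 8285 on the latter with no filter.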

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

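The counts of genes called under other groupings of the libraries were tests chosen after the results were seen; the tests of scaling and of dilution were set before.

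The results below stand out because the ligule difference was not the same in the adaxial L1 as in all layers. For 506 genes that difference was called. Of 100 groupings of the same libraries, only the real 1 called as many (1 of 100). The highest others called 442, 383 and 368, and these 3 groupings kept the 3 ligule libraries of the adaxial L1 together, while the next called 46. The groupings mixed the regions within both sets, so most of them also broke up the ligule difference of each set. Their counts thus do not test whether that difference is the same in both sets. The layer comparison itself called 7536 genes with at most 79 in the other groupings (1 of 100 reached the real count).

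Why ligule differences were mostly more negative in the adaxial L1 was weighed between scaling, dilution by inner tissue and low counts. After the median of -0.07 was removed, 81.4% of calls (394 of 484) were still lower, so an offset of that size is not the whole cause. TMM factors already bring most genes near 0, so this test could not exclude an error of the scaling itself. Inner tissue may dilute a difference of the epidermis in the all-layers pieces, because over the 554 genes higher in the ligule of the adaxial L1 the interaction fell with the layer difference (Spearman -0.49, permutation p = 1e-05, the smallest that 100000 permutations can give, with genes that are not independent replicates). The same correlation could arise if low levels in the adaxial L1 give larger fitted folds, which was not tested, and it does not concern the 426 lower calls. The 554 genes were chosen for a rise in the adaxial L1, which is a part of the interaction. Low blade and sheath levels there raise the interaction and lower the layer difference, so part of the correlation may be built in. The layers were separate sets of libraries with different depth, so this stays open.

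Among genes with a lower ligule difference in the adaxial L1, with that difference in all layers and in the adaxial L1 in brackets, the interaction was -6.38 (SE 0.38, adjusted p = 2.9e-09) for dehydrin3 (-0.3 and -6.64). It was -5.08 (SE 0.55, adjusted p = 3.3e-05) for mips2 (-2.31 and -7.3) and -4.95 (SE 0.71, adjusted p = 0.00036) for GRF7 (-2.15 and -7.07). GRAS19 had -3.35 (SE 0.44, adjusted p = 0.00014; -0.39 and -3.73), AR2 -2.56 (SE 0.52, adjusted p = 0.0079; -1.62 and -4.14) and opr8 -2.53 (SE 0.48, adjusted p = 0.0048; -0.07 and -2.55). For acco20 it was -2.44 (SE 0.51, adjusted p = 0.011; -1.68 and -4.09), for GRF11 -2.34 (SE 0.46, adjusted p = 0.0064; -1.16 and -3.46) and for CesA-7 -1.94 (SE 0.38, adjusted p = 0.0065; 0.66 and -1.24). For rs2 it was -1.88 (SE 0.32, adjusted p = 0.0019; -0.16 and -2), for lox4 -1.83 (SE 0.36, adjusted p = 0.0065; -2.74 and -4.53) and for HSF2 -1.82 (SE 0.37, adjusted p = 0.009; -0.58 and -2.36). For lox5 it was -1.52 (SE 0.31, adjusted p = 0.0084; -0.89 and -2.37) and for sus1 -1.42 (SE 0.3, adjusted p = 0.011; -1.01 and -2.38).

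A higher ligule difference in the adaxial L1 was found for PIN1a at 3.1 (SE 0.54, adjusted p = 0.0021; -0.02 and 3.13), RR6 at 2.84 (SE 0.48, adjusted p = 0.0015; 0.51 and 3.4) and ARF23 at 2.3 (SE 0.57, adjusted p = 0.033; 0.57 and 2.92). Other calls were lost when 1 library was left out. These were AUX18 at -9.73 (SE 1.98, adjusted p = 0.01; 0.92 and -8.06) and YAB5 at 5.15 (SE 1.14, adjusted p = 0.018; 0.59 in all layers, not tested in the adaxial L1), each lost without ligule replicate 3 of the adaxial L1. The pck2 value of 8.1 (SE 1.79, adjusted p = 0.02; 1.09 in all layers) was lost without that library or ligule replicate 3 of all layers. CER1 at -2.14 (SE 0.47, adjusted p = 0.015; 0.78 and -1.32) was lost without ligule replicate 3 of all layers. The calls of rbcS at -8.16 (SE 2, adjusted p = 0.035; -0.13 and -7.6), ivr2 at -2.49 (SE 0.63, adjusted p = 0.039; 0.98 and -1.47), ub2 at -1.83 (SE 0.44, adjusted p = 0.025; -0.77 and -2.57) and EXPA5 at 1.89 (SE 0.46, adjusted p = 0.031; 0.37 and 2.3) were lost without any of 5 or more libraries. Folds fitted against groups without counts are not measured sizes; for AUX18 and rbcS the ligule of all layers was at least 159-fold and 197-fold above that of the adaxial L1.

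For lists the median interaction was -1.16 for jasmonate genes (adjusted p = 0.00077; medians -0.11 and -0.7), 0.52 for ribosomal protein genes (adjusted p = 7.7e-08; -0.57 and -0.07) and -1.24 for starch and sugar genes (adjusted p = 0.003; 0.11 and -1.14). It was -0.67 for cell wall synthesis (adjusted p = 0.0072; 0.21 and -0.67), -0.62 for HD-ZIP IV genes (adjusted p = 0.032; -0.52 and -1.02), -3.49 for carbon fixation and C4 (adjusted p = 0.022; 0.21 and -0.6) and 0.27 for cytokinin genes (adjusted p = 0.033; 0.45 and 0.58). With an estimated correlation the adjusted p-values ran from 0.054 to 0.29, so none of the 7 kept its call. The cell wall synthesis call was lost without ligule replicate 5 of all layers (-0.57). The HD-ZIP IV call was lost without blade 3 (-0.61), ligule 5 (-0.49) or sheath 3 (-0.57) of all layers, or ligule 1 (-0.55), ligule 2 (-0.45) or sheath 3 (-0.53) of the adaxial L1, with adjusted p-values up to 0.16. The cytokinin call was lost without ligule 5 of all layers (0.27), or blade 3 (0.3), ligule 1 (0.24), ligule 2 (0.33) or sheath 1 (0.43) of the adaxial L1, and its median was 0.56 without ligule 4 of all layers and 0.5 and 0.54 without blade 1 and sheath 2 of the adaxial L1.

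The carbon fixation and C4 call was lost without blade 3 (-1.53), blade 4 (-1.96), ligule 3 (-1.58), ligule 5 (-1.6) or sheath 4 (-1.33) of all layers, or blade 3 (-1.27), ligule 1 (-1.16), ligule 2 (-1.3) or sheath 3 (-1.41) of the adaxial L1, and with no filter (-1.24). It was kept with a median nearer 0 without blade 5 (-1.28) or ligule 4 (-1.4) of all layers, or blade 1 (-1.45), blade 2 (-1.29), sheath 1 (-1.35) or sheath 2 (-1.58) of the adaxial L1. With genes at 0 set to their bound its median was -1.62, so -3.49 is not a measured size. TCP5 was called between blade and sheath in the adaxial L1 (-2.03, SE 0.43, adjusted p = 0.027) and not in all layers (0.65), a difference that was not tested.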

How the results depend on the processing

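Leaving out together the libraries that stand apart was a choice made after the results were seen. Of 5211 settings of named genes, 4734 kept their side of the threshold, 467 lost the call, 8 gained it and 2 reversed, and of 833 list settings 691 kept their call, 142 lost it and 0 reversed. The reversals were pck2 in the interaction, -0.09 with limma on log2(FPKM + 1), with or without the filter; the cause was not tested.

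With 1 library left out, the ligule against the mean called 639 to 1223 genes in all layers and 826 to 1438 in the adaxial L1. The ligule against the blade called 598 to 1600 and 706 to 1224, against the sheath 374 to 578 and 640 to 1322, and blade against sheath 113 to 355 and 201 to 397. The P6 comparison called 0 to 58, the interaction 338 to 562 and the layer comparison 6865 to 7891. Median changes in lg1-R were -0.36 to -0.12 and 0.02 to 0.22 for genes higher and lower in the ligule of all layers, and -0.05 to 0.06 and 0 to 0.16 for those of the adaxial L1. These fits hold fewer libraries.

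With no filter more genes were tested and 1890, 1984, 1214 and 827 were called in all layers (ligule against mean, blade and sheath, then blade against sheath), 2317, 1886, 1872 and 906 in the adaxial L1, 482 at P6 and 1029 in the interaction. DESeq2 called 1672, 1784, 1073 and 689, then 2425, 2133, 2254 and 993, 150 at P6 and 1003 in the interaction. A fit of all 24 libraries called 352 against the sheath and 166 between blade and sheath in all layers, 3858, 3495, 3558 and 1786 in the adaxial L1, 0 at P6 and 816 in the interaction. Calls in both pairwise comparisons numbered 404 and 631. Limma on log2(FPKM + 1) with no filter called 153 between blade and sheath of all layers, and 0 at P6 with or without the filter; the 1 gene of log2(FPKM + 0.1) was another gene. Without the libraries that stand apart, the ligule against the blade called 1600 in all layers and P6 called 0. The causes were not tested. RLE factors moved no count by over 1.5 times. The share of higher calls between layers went from 38% to 14.9% to 18.7% with limma, that of the interaction from 15.8% to 26% without the libraries that stand apart, and that of the ligule of all layers from 60% to 72.6% with limma and no filter. With limma and no filter it also went from 57.7% to 69.2% against the blade and from 50.9% to 69% against the sheath of all layers. Against the blade of the adaxial L1 it went from 34.8% to 45.8% with limma on log2(FPKM + 1), and in both pairwise comparisons of the adaxial L1 it was 26.8%, from 38.2%. Between blade and sheath of the adaxial L1 it went from 43.9% to 53% with no filter, 56.6% in a fit of all 24 libraries and 31.9% with limma on log2(FPKM + 0.1).

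For the ligule genes in lg1-R, camera with a preset correlation called the sets with medians of -0.27, 0.11 and 0.05 without adjustment over the sets, which fry did not, and the cause was not tested. Fry called 2 sets without adjustment, the genes called in both pairwise comparisons of all layers (-0.52) and the genes higher in the ligule of all layers without wild-type replicate 3 (-0.36).

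The labels tie no numbers to plants, and not every same-numbered pair of libraries correlated above 0.1, so the numbers were not taken to pair the libraries. Same-numbered libraries correlated between -0.45 and 0.41 in all layers (5 of 9 libraries best with their own number), -0.05 and 0.04 in the adaxial L1 (2 of 9) and -0.17 and 0.04 at P6 (1 of 6). In all layers the same-numbered blade and ligule libraries did go together (0.41, 0.35 and 0.23), as did sheath 5 with its number (0.27 and 0.26), while sheath 3 and 4 went against theirs (-0.45 to -0.2). The block below uses the numbers as labelled, so its all-layers counts may rest on wrong numbers for these 2 sheath libraries; no fit with exchanged numbers was made. With a replicate block 185 genes were called between blade and sheath of all layers and 4 at P6; the other counts, 759, 769 and 431 in all layers, 1258, 1019, 913 and 300 in the adaxial L1 and 406 in the interaction, moved by less than 1.5 times. Medians in lg1-R with the block were -0.28, 0.11, -0.02 and 0.05, none called by fry.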

Other observations

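The counts of genes under other groupings, the test of sequence linked to lg1 and the test of inner tissue in the sheath pieces were chosen after the results were seen.

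The genes called in the ligule in all 4 pairwise comparisons were also looked up at P6, where none of them was called singly and no set test was run on them. Of 49 tested genes that were higher in all 4, 41 lay below 0 in lg1-R (median -0.62), and of 66 that were lower in all 4, 37 lay above 0 (median 0.1), where 51.3% of all tested genes lay below 0. Beside glu1, the genes with the smallest p in lg1-R included others that were higher in the P7 ligule of all layers. Examples were GRMZM2G366873 (-5.03, SE 0.65, in lg1-R and 5.93 in the ligule), GRMZM2G004106 (-4.13, SE 0.67, and 5.21) and gols2, a galactinol synthase gene (-3.23, SE 0.54, and 2.7), all with an adjusted p = 0.082 in lg1-R. Conversely, EREB20 was higher in lg1-R (1.78, SE 0.28) and lower in the ligule of all layers (-2.35). Genes higher in the sheath than the blade of all layers had a median of -0.29 in lg1-R (204 genes, adjusted p = 0.78 by fry), and genes higher in the blade 0.09 (100 genes, adjusted p = 0.87). For the adaxial L1 these medians were -0.12 (198 genes) and 0.21 (155 genes), with an adjusted p = 0.78 for each.

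The 9 genes called higher in the ligule of all layers and lower in that of the adaxial L1 had no names; GRMZM2G453139 was at 2.83 (SE 0.24) and -4.41 (SE 0.89), and GRMZM2G054115 at 2.06 (SE 0.35) and -5.77 (SE 1.36). All 265 counts of lg3 in the blade of the adaxial L1 came from replicate 1, and kn1, with 486 counts there, varied more between libraries than its mean (5.85 ± 7.71 CPM). The highest FPKM in sheath replicate 5 of all layers was 264521, against at most 48457 in the other libraries.

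Between lg1-R and wild type 1 gene was called, and the genes higher in the ligule of all layers had a median of -0.27, a shift that did not pass fry (adjusted p = 0.65). Genes of the chromosome carrying lg1 were 0.97 times as frequent among genes at an unadjusted p below 0.05 as among the others. The interval of the matching odds ratio was 0.78 to 1.19. The whole chromosome thus held no excess of such genes. A short stretch around lg1 and the shift of the ligule genes were not tested so, and sequence from another line stays open as a cause. A dissection at another height along the leaf could give such a shift. Genes higher in the blade and genes higher in the sheath differed by 0.38 in lg1-R (0.31 without genes called in the ligule), though fry called neither set. Genes lower and genes higher in the ligule also differed by 0.38. Without genes called between blade and sheath they still differed by 0.36, so these values do not decide on the height. The shift kept its sign without each library, at -0.12 without wild-type replicate 1. Every grouping of the 6 libraries kept wild-type replicate 1 in the wild-type group, so the sign is given relative to that library. In the 9 other groupings the median also lay below 0, from -0.36 to -0.09 (2 of 10, the real 1 included, reached -0.27). The groupings are too few, and the shift may come from differences among libraries of the same genotype. Loss of LG1 function stays possible as well, with lg1 itself not lower in the libraries labelled lg1-R. Genes such as ns1, glu1 and bHLH165 were already low in the P6 wild type. The single call thus does not show that few genes depend on LG1.

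For the other sets the real medians were 0.11, -0.02 and 0.05, reached by 5, 10 and 8 of 10 groupings, with the values farthest from 0 at -0.24, -0.14 and -0.21. Their signs too are given with wild-type replicate 1 in the wild-type group. At P6 the real grouping called 1 gene and the highest other 2 (2 of 10 called as many as the real 1).

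Photosynthesis genes were lower in the blade than in the sheath of all layers, with a median of -1.4 for the light reactions. The sheath library that stood apart is not the cause, as the median without sheath replicate 4 was -1.44. A larger share of inner or older, chlorophyll-bearing tissue in the sheath pieces might contribute, since the 6 members tested in the adaxial L1 had a median of 0.17 (-0.59 to 1.05), but the same 6 had only -0.44 in all layers, so this remains open. A difference in how far the cells of both regions have matured was not tested.

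The ligule against the mean of blade and sheath called 1014 genes in all layers and 1451 in the adaxial L1, a count reached by 1 of 100 groupings each, with 687 and 105 in the highest other. The all-layers grouping with 687 calls put blade replicate 3, ligule replicate 3 and sheath replicate 4 together, and the deviations of these 3 from their group means correlated at 0.41, 0.4 and 0.48. Blade replicate 4, ligule replicate 4 and sheath replicate 3 also deviated together (0.35, 0.31 and 0.47), as did the 3 libraries numbered 5 (0.23, 0.27 and 0.26). For the pairwise comparisons 10 groupings exist, too few for a test; against blade, against sheath and between blade and sheath the real counts were 1054, 619 and 350 in all layers with 0, 1 and 0 in the highest other, and 1216, 1158 and 367 in the adaxial L1 with 0, 0 and 1 (1 of 10 each).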
